A study of Cavia porcellus with 13 samples.

How the data were processed

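The 13 libraries were made from total RNA of guinea pig skin, isolated with a Qiagen RNeasy kit and prepared by Illumina protocols, per the labels' protocols. The values used are TPM (a gene's length-scaled share of each library's transcripts) as the authors deposited them, in a single file with 26855 genes and a column per library, each column summing to 1000000. Trimmomatic, StringTie and DESeq are named in the submitters' processing notes, without versions or roles; the aligner, genome build and annotation release are not given in the sources used here. Because TPM divides out gene length and depth, a TPM is a share of the library, so a gain in 1 abundant tissue lowers the others, and the depth of each library is unknown. Of the genes, 18254 carry a symbol in the deposited table and 8601 do not. The RefSeq table at hand carries no Ensembl identifiers, so 0 of those 8601 could be named and no coordinates are given; they are printed as identifiers.

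All choices of groups, tests, gene lists, alternatives and the rule for named genes were made before the data were examined, except the 2 alternatives and the tests said to be chosen later. A gene entered the tests with at least 1 TPM in at least 2 libraries, which left 14979 genes, 2890 of them without a symbol. Differences were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (values read with the data.table package, version 1.17.8), empirical Bayes with an intensity trend and Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes. The prefix of the library titles was taken as the experiment and entered as a fixed term. Bitten against naive skin used a bitten term over all libraries; the other 7 comparisons came from 1 model of 5 groups and the experiment, whose residual spread all groups share. In it, first exposure and saliva immune skin rest on naive replicates 1 and 2, and 2 bites and 3 bites skin on naive replicate 3 alone, which is assumed to vary like the other groups. Comparisons against the same naive libraries share their chance values, so they are not independent of each other, and no overlap between them was counted.

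Gene lists of 34 kinds were fixed by symbol: immune cells (neutrophil, mast cell and basophil, eosinophil, T cell, cytotoxic and natural killer cell, B cell and plasma cell, monocyte and macrophage, dendritic and Langerhans cell), immune responses (inflammatory cytokines and chemokines, interferon gamma and type 1, type I interferon, type 2, type 17, regulatory, complement and coagulation, itch, histamine and pain sensing), skin and other tissue (epidermal differentiation, activated keratinocyte, basal keratinocyte, hair follicle, sebocyte and lipid synthesis, adipocyte, skeletal muscle, smooth muscle and pericyte, fibroblast and extracellular matrix, matrix remodelling enzymes, endothelial cell, melanocyte, nerve and Schwann cell, erythroid and platelet) and general programmes (cell cycle, immediate early and stress, oxidative phosphorylation, ribosomal protein). Of their 698 entries, 522 were in the table and 443 passed the filter, matched without regard to case. Lists with at least 5 measured members (32 of them) were tested with camera in limma at a preset correlation of 0.01, adjusted over all 256 pairs of list and comparison. camera sets a list against all other genes, so its direction is relative to them. camera with a correlation estimated per list, and fry, were the alternatives: the first called 0 and fry 0 after adjustment (smallest adjusted p = 0.419) against 96 in the main test, with 23 pairs at an unadjusted p under 0.05 by fry.

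The named genes are those called with a symbol and at least 5 TPM in the higher group, with no overlap between the libraries compared, up to 8 each way, plus the 4 members of each list with the smallest p in that comparison and a fixed panel of cytokine and cell marker genes. A called gene outside that rule (ENSCPOG00000008260, ENSCPOG00000036317, ENSCPOG00000035456) is named because the counts are small, and was chosen after its values were seen. Symbols are printed as the table gives them.

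The median log2 difference over all tested genes was 0.10 in bitten against naive, 0.14 in first exposure and 0.14 in saliva immune against naive, 0.02 between those 2 groups, -0.06 in 2 bites and 0.08 in 3 bites against naive, 0.14 between 3 and 2 bites and -0.10 for repeat bites against first exposure. Median-of-ratios scaling brought these to between -0.03 and 0.03, a shift of over 0.1 in several comparisons, and turned the sign of no called list. Of the 46 ribosomal protein and oxidative phosphorylation genes in the table, 0 were listed at 0 in any library.

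The fits were tested on simulated data: for each comparison, 200 of the 14979 genes were changed by known log2 sizes of 1, 2 or 3. At sizes 1, 2 and 3, limma recovered 62.1%, 94.0% and 95.5% in bitten against naive, 40.9%, 80.6% and 95.5% in first exposure against naive, 40.9%, 82.1% and 95.5% in saliva immune against naive and 43.9%, 74.6% and 94.0% between those 2 groups. It recovered 19.7%, 58.2% and 71.6% in 2 bites against naive, 16.7%, 56.7% and 89.6% in 3 bites against naive, 24.2%, 74.6% and 86.6% between 3 and 2 bites, and 3.03%, 44.8% and 71.6% for repeat bites against first exposure. As a share of calls, genes that had not been changed ranged from 4 of 113 (3 bites against naive) to 11 of 157 (saliva immune against naive). Of 200 random lists per comparison, 0 to 6 had an unadjusted camera p under 0.05. The simulated genes varied independently of each other, so this says nothing about the preset correlation on which the list calls rest. The simulated libraries also held no differences between experiments or in muscle content. With 200 changed genes, more than limma called in any real comparison, the adjustment is less strict as well. The shares recovered and falsely called are therefore not those of the tests on the real libraries.

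Alternatives were a pseudocount of 0.1, no filter, a filter on mean TPM, median-of-ratios scaling, quantile normalization, no experiment term, each experiment fitted alone, array weights, leaving out each library in turn, and for lists the 2 other set tests. Added after seeing the data were the skeletal muscle score (the mean of that list per library) as a covariate, and leaving out together naive replicate 2, with the most muscle RNA, and 2 bites replicate 1, with the most macrophage and matrix enzyme RNA.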

Results

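Skin RNA of guinea pigs was profiled by sequencing in 13 libraries to ask how the response at a tick bite differs between animals bitten before and animals bitten for the first time. All libraries carry day 4 after attachment as their time point, and the naive skin, given the same day, had no bite. The bitten skin fell into 4 groups: a first exposure (3 libraries), animals labelled as immune to tick saliva and then bitten (3, the way of immunization not being given), 2 bites (2) and 3 bites (2). Naive skin had 3 libraries. The library titles carry 2 prefixes, CK1 and EF19-5, which the labels do not explain; they were taken as 2 experiments. That choice sets the naive reference of each group, and without it 2 bites against naive skin went from 2 to 254 called genes and 9 called gene lists turned sign. CK1 held the first exposure and saliva immune groups with naive replicates 1 and 2 (8 libraries), and EF19-5 held the 2 bites and 3 bites groups with naive replicate 3 (5 libraries). Between 13270 and 14391 genes per library reached 1 TPM. TPM values keep no record of depth, so the depth behind each value is unknown. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples, which may in part be technical.

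Skeletal muscle transcripts took very different shares of the libraries. Genes of the skeletal muscle list, contractile and metabolic genes of muscle fibres, made up 15.6% of summed TPM in naive replicate 2, 8.93% in naive replicate 1 and 2.20% in naive replicate 3. The first exposure libraries held 4.22% to 6.32%, the saliva immune libraries 2.19% to 9.38%, the 3 bites libraries 0.703% and 1.38%, and the 2 bites libraries 0.562% and 0.754%. Hair follicle genes took from 0.588% (saliva immune replicate 2) to 3.24% (2 bites replicate 2). The first principal component held 44.3% of the variance and PC2 15%. Libraries of the same group and experiment correlated with Pearson's r of 0.933 to 0.98 across genes, which are not independent replicates, and libraries of different groups or experiments with 0.866 to 0.982; no 2 libraries were identical.

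**Figure D1:**
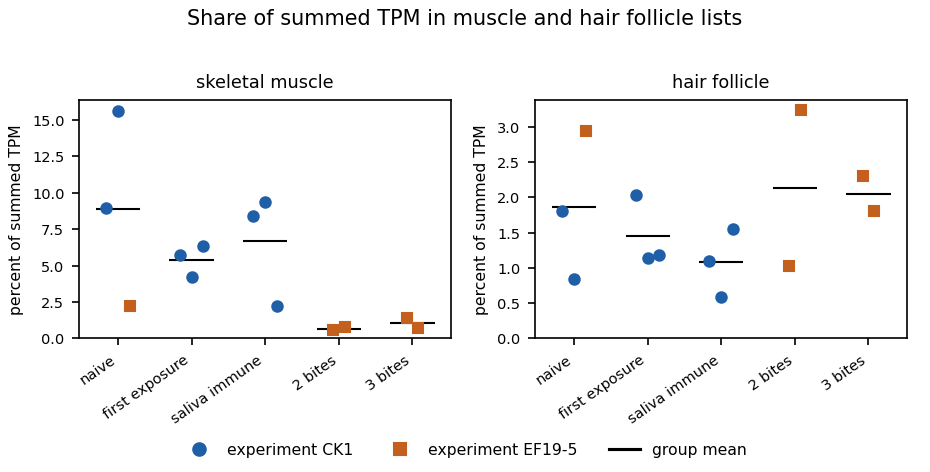
Share of summed TPM, in percent (y axis, linear, from 0), taken by the skeletal muscle and hair follicle lists in each of the 13 libraries, by group (x axis); points are libraries, shaped and coloured by experiment, and lines are group means. The muscle share runs from 0.562% in 2 bites replicate 1 to 15.6% in naive replicate 2.

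Bitten skin of all 4 groups was first set against naive skin. A gene with no symbol in the deposited table, ENSCPOG00000008260, was listed at 0 in all 3 naive libraries and lay between 422 and 1365 TPM in all 10 bitten ones. It stood at 507 ± 57.8 TPM in first exposure (SD, n = 3), 451 ± 50.2 in saliva immune (n = 3), 613 ± 154 in 3 bites (n = 2) and 1262 ± 146 in 2 bites skin (n = 2). KLK13, a kallikrein serine protease, rose from 9.53 ± 3.76 TPM in naive (n = 3) to 52.2 ± 32.0 in bitten skin (n = 10), with a log2 fold change of 2.11 (SE 0.328). Within CK1 it stood at 34.9 ± 18.2 in first exposure and 31.7 ± 4.72 in saliva immune against 7.87 ± 3.42 in naive skin, and within EF19-5 at 103 ± 29.9 in 2 bites and 58.3 ± 16.5 in 3 bites against 12.9 in the naive library. CDHR1, a cadherin-related protein known from photoreceptors, rose from 0.819 ± 0.481 to 7.89 ± 4.61 TPM. PVALB, the calcium-binding parvalbumin of fast muscle fibres, fell from 1604 ± 905 to 372 ± 124 TPM (log2 fold change -1.97), in the comparison whose naive CK1 libraries carried 8.93% and 15.6% muscle transcripts.

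limma called 6 of 14979 genes in bitten against naive skin, 4 higher and 2 lower. Adjusted p was 1.62e-10 for ENSCPOG00000008260, 0.0499 for KLK13 and for CDHR1 and 0.0413 for PVALB. The other 2 have no symbol: ENSCPOG00000036317, listed at 0 in the naive libraries and at 1.05 to 2.19 TPM in the bitten ones (adjusted p = 0.0179), and ENSCPOG00000035456, which fell from 5.65 ± 3.04 to 0.234 ± 0.406 TPM (adjusted p = 0.0191). At an unadjusted p under 0.05, 1680 genes were higher and 686 lower, where 749 in all are expected by chance. ENSCPOG00000008260 passed in all 22 other fits, while ENSCPOG00000036317 passed in 18, ENSCPOG00000035456 in 16, PVALB in 9 and KLK13 and CDHR1 in 6 each, with adjusted p of up to 0.403 for KLK13. The count was 1 without first exposure replicate 3 or naive replicate 2, and 3 without first exposure replicate 2, saliva immune replicate 1 or naive replicate 1. It was 11 without 3 bites replicate 2, 17 without first exposure replicate 1 and 31 without 3 bites replicate 1. Without naive replicate 3, where the contrast rests on CK1 alone, the count was 16. Array weights (0.445 to 2.65) gave 92 calls, 63 higher and 29 lower, and a pseudocount of 0.1 gave 12, 11 higher and 1 lower. Quantile normalization and leaving out the experiment term gave 3 each (2 higher, 1 lower), the skeletal muscle score as a covariate 3 (all higher), and leaving out naive replicate 2 with 2 bites replicate 1 gave 1.

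**Figure D2:**
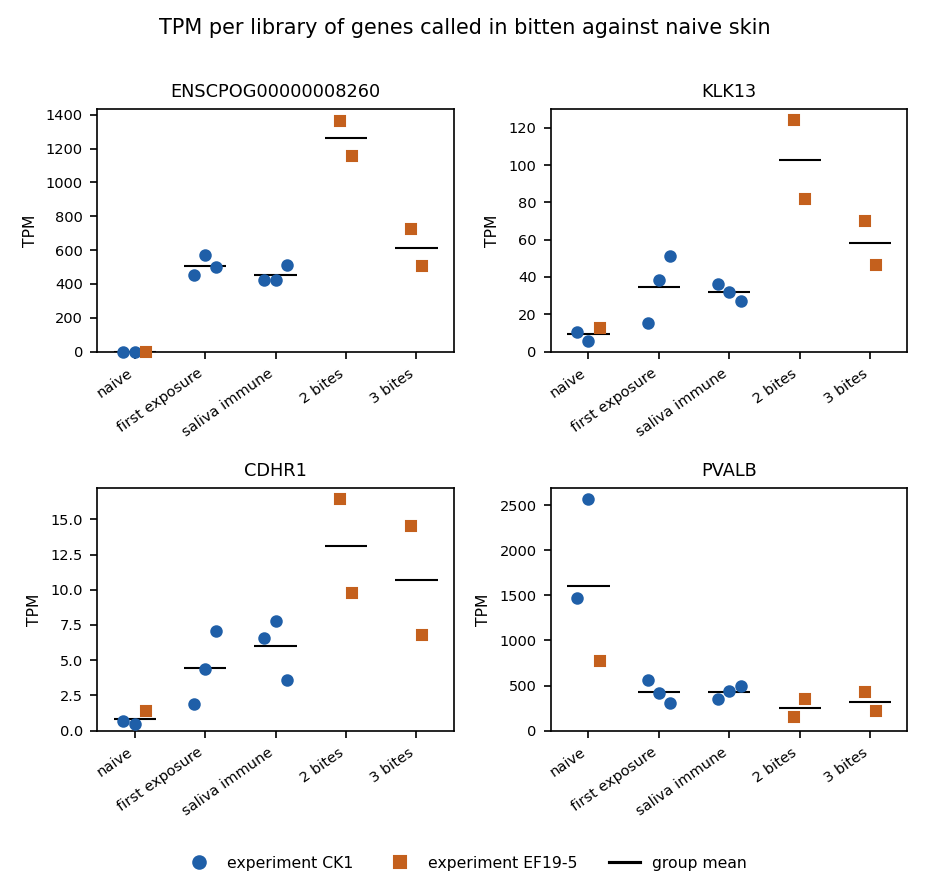
TPM (y axis, linear, from 0) of ENSCPOG00000008260, KLK13, CDHR1 and PVALB in each library, by group (x axis); points are libraries, shaped and coloured by experiment, and lines are group means. ENSCPOG00000008260 is listed at 0 in the 3 naive libraries and lies at 422 TPM or more in the 10 bitten ones.

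Of the 15 tested lists of immune cells and responses, camera called 7 higher in bitten than in naive skin at the preset correlation and 0 with an estimated correlation (adjusted p = 0.86 to 0.898 for the called lists of this comparison). The other 8 were not called at the preset correlation: cytotoxic and natural killer cell (adjusted p = 0.129), B cell (0.769), dendritic cell (0.206), inflammatory cytokines (0.087), type 2 (0.281), type 17 (0.0977), regulatory (0.0558) and itch (0.14). The muscle share, 0.562% to 9.38% in bitten libraries and 2.20%, 8.93% and 15.6% in naive ones, differed between the same groups. All 14 measured genes of the monocyte and macrophage list were higher, with a mean log2 difference of 0.97 (1.02 within CK1 and 0.88 within EF19-5) against a median of 0.10 over all genes. CD68, a lysosomal protein of macrophages, stood at 80.5 ± 28.0 TPM in bitten (n = 10) and 38.1 ± 22.7 in naive skin (n = 3), and CD14, a co-receptor for bacterial lipopolysaccharide, at 21.5 ± 10.7 and 8.69 ± 5.54. The neutrophil list differed by 0.85 (7 of 8 members higher), with the calprotectin subunit S100A9 at 677 ± 615 against 119 ± 39.0 TPM. The mast cell and basophil list differed by 0.68 (11 of 11), with the mast cell protease CPA3 at 2.96 ± 2.11 against 0.938 ± 0.725 and HDC, which makes histamine, at 1.59 ± 1.31 against 0.252 ± 0.0180. The T cell list differed by 0.56 (11 of 11), with the T cell receptor chain CD3E at 4.32 ± 2.10 against 1.65 ± 0.832. The type I interferon response list differed by 0.60 (11 of 12), with the antiviral enzyme RSAD2 at 1.96 ± 0.605 against 0.670 ± 0.317, and the interferon gamma list by 0.64 (10 of 10), with the transcription factor IRF1 at 25.1 ± 10.4 against 12.1 ± 4.04. Complement and coagulation genes differed by 0.52 (16 of 20), with C3, the central complement component, at 63.9 ± 23.3 against 24.8 ± 8.58.

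Some lists of resident skin cells moved too, at the preset correlation only (smallest camera adjusted p = 0.86 with an estimated correlation). The smooth muscle and pericyte (-0.155), fibroblast (-0.05), melanocyte (-0.068) and nerve and Schwann cell lists (0.129) were not called. The epidermal differentiation (mean log2 difference 0.55, 14 of 14 higher), basal keratinocyte (0.46, 10 of 10), sebocyte and lipid synthesis (0.47, 20 of 20) and endothelial cell lists (0.50, 13 of 15) lay higher, as did ribosomal protein genes (0.17, 21 of 22). The adipocyte list differed by 0.95 when pooled; the difference held within CK1 (1.60) but not within EF19-5 (-0.25), which has 1 naive library. The adipokine ADIPOQ stood at 719 ± 399 TPM in bitten and 234 ± 138 in naive skin, while GPD1, a glycerol phosphate enzyme on the same list, lay lower at 131 ± 79.0 against 260 ± 147. Skeletal muscle genes lay lower (-0.77), among them ACTN3, an actinin of fast fibres, at 534 ± 420 against 2687 ± 2151 TPM. Immediate early and stress genes also lay lower (-0.62; 19 of 20), with the stress factor ATF3 at 35.8 ± 18.6 against 139 ± 109 and FOSB, a subunit of the AP-1 transcription factor, at 37.4 ± 28.1 against 169 ± 173. Cell cycle genes differed by -0.18 (-0.33 within CK1 and 0.10 within EF19-5), hair follicle genes by -0.18 (0.03 within CK1 and -0.56 within EF19-5) and oxidative phosphorylation genes by -0.07. The naive libraries of CK1, where these differences are largest for adipocyte genes, held 8.93% and 15.6% muscle transcripts. The means moved by over 1.5 times in some fits without a library. Leaving out naive replicate 1 moved the mean to 0.86 for epidermal differentiation, 0.73 for basal keratinocyte, -0.01 for hair follicle, -0.35 for immediate early and -0.15 for oxidative phosphorylation genes. Leaving out naive replicate 2 gave a mean of 0.23 for epidermal differentiation, 0.21 for basal keratinocyte, -0.51 for hair follicle, 0.24 for sebocyte, 0.48 for adipocyte, -0.07 for cell cycle and -0.03 for oxidative phosphorylation genes. The adipocyte mean was 0.50 without that library and 2 bites replicate 1 together. In that fit camera at the preset correlation called 14 of 32 lists, against 18 with all libraries. The mean without naive replicate 3 was 1.60 for adipocyte, -0.33 for cell cycle and -0.01 for oxidative phosphorylation genes. These are the differences within CK1, since that library is the only naive one of EF19-5. Hair follicle and oxidative phosphorylation means also moved, to -0.29 for hair follicle genes without first exposure replicate 1, -0.07 for hair follicle and -0.11 for oxidative phosphorylation genes without saliva immune replicate 2 and -0.06 for hair follicle genes without 2 bites replicate 1. A mean of -0.02 was found for oxidative phosphorylation genes without saliva immune replicate 3.

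camera called these 18 of 32 lists, 13 higher and 5 lower, with adjusted p from 6.45e-10 for skeletal muscle to 0.0331 for complement and coagulation, and none was called with an estimated correlation, where adjusted p lay between 0.86 and 0.898. By fry, 0 of the lists passed after adjustment and 10 at an unadjusted p under 0.05. In exact permutations of library scores, chosen after seeing the data, none of 24 scores passed after adjustment (smallest adjusted p = 0.0858). With 140 arrangements the smallest permutation p possible was 0.00714, at which 1 score alone could not pass over 24. That none passed therefore says little. Type I interferon genes lay at that smallest value, and skeletal muscle had an unadjusted permutation p of 0.143. No member of any list passed limma over all genes, in this or any other comparison. Adjusted over the list alone, 13 muscle, 10 adipocyte (9 higher), 6 immediate early, 5 type I interferon, 3 T cell, 3 interferon gamma, 2 mast cell, 1 neutrophil and 1 endothelial gene passed, and 0 in the other 9 lists. Without naive replicate 3, the only naive library of EF19-5, the contrast rests on CK1 alone and the adjustment on fewer pairs. There camera no longer called the neutrophil (adjusted p = 0.0574), mast cell (0.0896), type I interferon (0.0558) or complement list (0.163). Nor did it call the basal keratinocyte (0.133), endothelial (0.0968), oxidative phosphorylation (0.0896) or hair follicle list (0.203, mean 0.03). Without naive replicate 2, the adjusted p was 0.102 for epidermal differentiation, 0.12 for basal keratinocyte, 0.214 for cell cycle and 0.403 for oxidative phosphorylation genes. Without saliva immune replicate 2 it was 0.0544 for neutrophil, 0.111 for complement, 0.0722 for hair follicle and 0.0591 for ribosomal genes. Single further losses were complement without 3 bites replicate 1 (0.0505) or 2 bites replicate 1 (0.0786), hair follicle without 2 bites replicate 1 (0.0798) or naive replicate 1 (0.11), ribosomal without naive replicate 1 (0.316) or 2 bites replicate 2 (0.0513), and oxidative phosphorylation without saliva immune replicate 3 (0.14). With the muscle score as a covariate, chosen after seeing the data, adjusted p was 0.147 for epidermal differentiation, 0.189 for basal keratinocyte and 0.0585 for sebocyte genes, and oxidative phosphorylation genes were called higher (mean 0.12, adjusted p = 0.00393). Still called with that covariate, but with means moved by over 1.5 times, were T cell (0.31), interferon gamma (0.42) and hair follicle genes (-0.32).

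**Figure D3:**
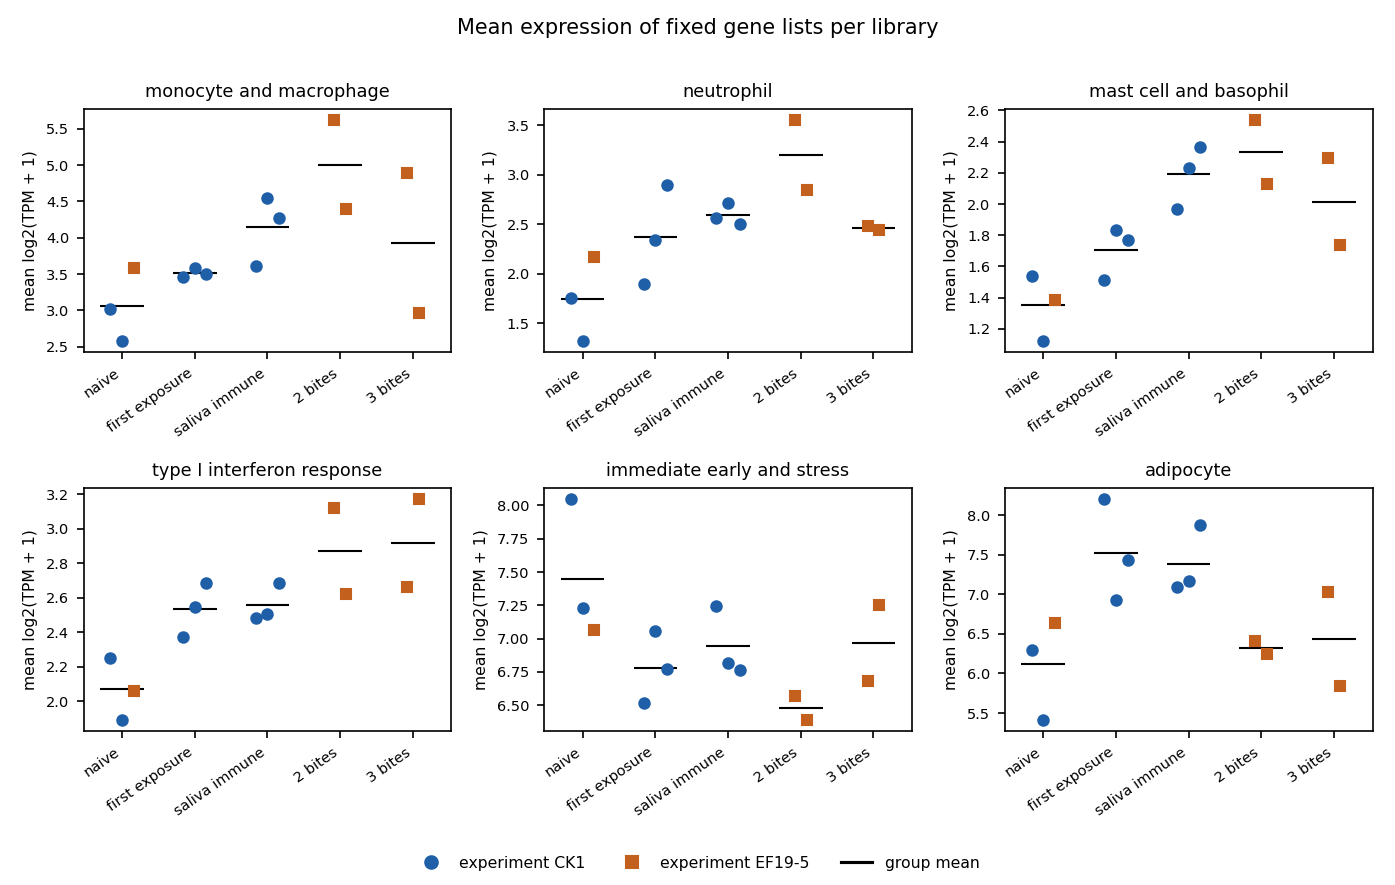
Mean log2(TPM + 1) over the measured members of 6 fixed gene lists (y axes, not starting at 0) in each library, by group (x axis); points are libraries, shaped and coloured by experiment, and lines are group means. The monocyte and macrophage mean runs from 2.59 in the lower naive library of CK1 to 5.62 in the higher 2 bites library, and the 3 bites libraries lie apart at 2.97 and 4.90.

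A first exposure was compared with the naive skin of its own experiment, CK1 (naive replicates 1 and 2). Adipocyte genes were higher as a group (mean log2 difference 1.67 against a median of 0.14 over all genes). camera called this list and those below at the preset correlation, but none with an estimated correlation (adjusted p = 0.86 to 0.909). The adipokine LEP (leptin) stood at 2839 ± 1455 TPM in first exposure (n = 3) and 321 ± 114 in CK1 naive skin (n = 2), and PPARG, the adipocyte transcription factor, at 24.7 ± 6.22 and 7.93 ± 4.09. The sebocyte and lipid synthesis list (0.71) lay higher, with the wax synthase AWAT1 at 51.1 ± 12.2 against 19.4 ± 8.95, and so did basal keratinocyte (0.61), epidermal differentiation (0.61) and ribosomal protein genes (0.27). Of the immune lists, interferon gamma (0.77) and T cell genes (0.57) lay higher. CXCL10, a chemokine induced by interferon, stood at 28.7 ± 25.3 against 4.25 ± 1.71. Immediate early genes lay lower (-0.85), with NR4A1, an immediate early nuclear receptor, at 35.5 ± 16.3 against 189 ± 35.6. Cell cycle genes also lay lower (-0.43, 22 of 23 members), with the nucleotide synthesis enzyme RRM2 at 14.8 ± 2.19 against 25.5 ± 4.19. Skeletal muscle (-0.56) and oxidative phosphorylation genes (-0.07) were lower, the muscle share being 4.22% to 6.32% in first exposure and 8.93% and 15.6% in CK1 naive skin. Single naive libraries moved several means by over 1.5 times. Leaving out naive replicate 2 moved the mean to 0.33 for T cell, 0.51 for interferon gamma, 0.11 for basal keratinocyte, 0.36 for sebocyte and -0.21 for skeletal muscle genes. Leaving out naive replicate 1 gave a mean of 1.22 for epidermal differentiation, 1.1 for basal keratinocyte, -0.91 for skeletal muscle, -0.45 for immediate early and -0.19 for oxidative phosphorylation genes. Means also moved to -0.37 for skeletal muscle genes without first exposure replicate 2 and -0.13 for oxidative phosphorylation genes without first exposure replicate 3.

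limma called 5 genes between first exposure and naive skin, 3 higher and 2 lower, and 2044 passed at an unadjusted p under 0.05. ENSCPOG00000008260 rose (adjusted p = 3.97e-09) and ENSCPOG00000035456 fell (log2 fold change -3.04, adjusted p = 0.033). CEP131, a centrosomal protein, fell from 29.7 ± 10.7 to 4.92 ± 1.39 TPM (log2 fold change -2.36, SE 0.307, adjusted p = 0.0492), the EF19-5 naive library standing at 5.27. A gene named Vault in the deposited table rose from 0.496 ± 0.0769 to 5.82 ± 0.337 TPM (adjusted p = 0.0455), with 5.40 in the EF19-5 naive library. The fifth gene has no symbol. Vault passed in 11 and CEP131 in 9 of 23 other fits, with adjusted p of up to 0.654 and 0.365. The fit on CK1 alone also called 5 genes, 1 higher and 4 lower, but neither of these (adjusted p = 0.104 for each). Quantile normalization gave 7 calls, 5 higher and 2 lower, the muscle covariate 37 (21 higher, 16 lower), no filter 3 (1 higher, 2 lower), leaving out naive replicate 2 with 2 bites replicate 1 2 and leaving out the experiment term 1. The count was 1 without any 1 of the first exposure libraries, saliva immune replicate 2, naive replicate 2, 2 bites replicate 1 or 2 bites replicate 2, 2 without naive replicate 1, 13 without either 3 bites library and 19 without saliva immune replicate 3. camera called 11 lists, with adjusted p from 6.45e-10 (cell cycle) to 0.0444 (T cell) and from 0.86 to 0.909 with an estimated correlation. Adjusted over the list alone, 11 adipocyte (10 higher), 5 immediate early and 2 muscle genes passed, and 0 in the other called lists. Without naive replicate 2, adjusted p was 0.0785 for muscle, 0.48 for basal keratinocyte, 0.877 for epidermal differentiation (mean -0.01), 0.524 for oxidative phosphorylation (0.06) and 0.0652 for T cell genes. T cell genes were also lost without naive replicate 1 (0.0981), first exposure replicate 2 (0.0655) or 3 (0.177), or saliva immune replicate 2 (0.0795) or 3 (0.0676). Interferon gamma genes were lost without first exposure replicate 3 (0.135) or naive replicate 1 (0.0643), ribosomal genes without the same libraries (0.0614 and 0.377), and epidermal differentiation (0.103), basal keratinocyte (0.0655) and oxidative phosphorylation genes (0.412, mean 0.00) without first exposure replicate 2. The muscle covariate ended the calls of T cell (adjusted p = 0.127), epidermal differentiation (0.0725), basal keratinocyte (0.0582) and oxidative phosphorylation genes (0.312, mean 0.08).

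Saliva immune skin was compared with the same naive libraries. Monocyte and macrophage genes lay higher (mean log2 difference 1.34 against a median of 0.14 over all genes, 14 of 14 members), with C1QB, a chain of complement C1q, at 95.9 ± 39.6 TPM (n = 3) against 20.8 ± 1.55 in CK1 naive skin (n = 2), and CD14 at 21.6 ± 5.58 against 5.64 ± 2.38. With an estimated correlation, camera called neither this list nor any other of this comparison (adjusted p = 0.86 to 0.899). Mast cell and basophil genes (0.86, 11 of 11) lay higher too, with HDC at 1.43 ± 0.352 against 0.254 ± 0.0250 and the prostaglandin D2 receptor Ptgdr2 at 3.30 ± 1.37 against 0.629 ± 0.523. Neutrophil genes differed by 1.06, with NCF1, a subunit of the NADPH oxidase, at 5.40 ± 2.08 against 0.988 ± 0.538. T cell (0.63), complement and coagulation (0.70) and type I interferon genes (0.49) were higher, with C3 at 75.5 ± 14.4 against 21.9 ± 9.86 and CMPK2, an interferon-induced kinase, at 5.87 ± 1.35 against 2.02 ± 1.22. Adipocyte genes differed by 1.52, with LIPE, the hormone-sensitive lipase, at 122 ± 45.2 against 28.6 ± 14.7. Immediate early (-0.70), cell cycle (-0.23), hair follicle (-0.16), skeletal muscle (-0.63) and smooth muscle and pericyte genes (-0.18) lay lower, with LMOD1, a leiomodin of muscle, at 17.6 ± 6.22 against 36.7 ± 9.43, while the pericyte gene RGS5 on the same list lay higher at 27.6 ± 4.00 against 14.2 ± 6.33. The muscle share was 8.42%, 9.38% and 2.19% in the saliva immune libraries. Here too, single libraries moved means by over 1.5 times. Leaving out saliva immune replicate 3 moved the mean to 0.42 for T cell, -0.45 for hair follicle and -0.36 for cell cycle genes. Leaving out naive replicate 2 gave a mean of 0.39 for T cell, 0.31 for type I interferon, 0.40 for complement, -0.64 for hair follicle, -0.28 for skeletal muscle, -0.39 for smooth muscle, -0.12 for cell cycle and -1.11 for immediate early genes. Others were -0.99 for skeletal muscle genes without saliva immune replicate 1, -1.04 for skeletal muscle and -0.02 for cell cycle genes without saliva immune replicate 2 and -0.97 for skeletal muscle and -0.29 for immediate early genes without naive replicate 1.

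limma called 1 gene in saliva immune against naive skin, ENSCPOG00000008260 (adjusted p = 4.8e-09), with 1742 at an unadjusted p under 0.05. Median-of-ratios scaling gave 3 calls (2 higher, 1 lower) and quantile normalization 4 (2 higher, 2 lower). A pseudocount of 0.1 gave 5, all higher, the muscle covariate 7 (4 higher, 3 lower), array weights, which did not converge, 20 (13 higher, 7 lower), no filter 2 (1 each way), and leaving out the experiment term or naive replicate 2 with 2 bites replicate 1 2 each. The count was 2 without first exposure replicate 1 or saliva immune replicate 1, 3 without saliva immune replicate 2 or 3, and 6 without either 3 bites library. camera called 12 lists, with adjusted p from 6.45e-10 (immediate early) to 0.0484 (type I interferon) and from 0.86 to 0.899 with an estimated correlation. Adjusted over the list alone, 9 adipocyte, 6 macrophage, 4 immediate early, 3 mast cell, 2 neutrophil, 2 smooth muscle and pericyte (1 higher), 1 type I interferon and 1 complement gene passed, and 0 in the other 4 lists. Without saliva immune replicate 2, adjusted p was 0.156 for neutrophil, 0.0891 for mast cell, 0.146 for T cell, 0.254 for type I interferon, 0.317 for complement and 0.274 for hair follicle genes (mean 0.19). Without naive replicate 1 it was 0.0729 for neutrophil, 0.0944 for type I interferon, 0.436 for hair follicle (mean 0.32) and 0.377 for smooth muscle genes (mean 0.02), and without saliva immune replicate 3 it was 0.0542 for T cell, 0.588 for skeletal muscle (mean 0.15) and 0.0998 for smooth muscle genes. Without naive replicate 2 it was 0.0657 for type I interferon and for cell cycle and 0.0919 for complement genes, and type I interferon genes were also lost without first exposure replicate 2 (0.057), saliva immune replicate 1 (0.0523) or naive replicate 3 (0.0531). With the muscle covariate, T cell and type I interferon genes were not called (adjusted p = 0.0613 for each), and the hair follicle mean was -0.34.

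The saliva immune and first exposure groups were then set against each other. Macrophage genes lay higher in saliva immune skin (mean log2 difference 0.63 against a median of 0.02 over all genes, 14 of 14 members), with C1QC, a C1q chain, at 72.6 ± 27.7 TPM (n = 3) against 30.5 ± 1.91 in first exposure (n = 3). These and the list differences that follow were called at the preset correlation of camera only (adjusted p = 0.86 to 0.894 with an estimated correlation). Mast cell and basophil genes (0.48, 11 of 11), complement and coagulation (0.34), fibroblast and extracellular matrix (0.40) and cell cycle genes (0.20, 22 of 23) lay higher as well. Fibronectin, FN1, stood at 87.5 ± 9.58 against 25.3 ± 2.29 and fibrillin, FBN1, at 30.2 ± 2.66 against 11.5 ± 3.64. Type 2 response (-0.18, 11 of 14 lower), basal keratinocyte (-0.33), hair follicle (-0.37) and sebocyte genes (-0.25) lay lower. On the type 2 list the arginase ARG1 stood at 7.00 ± 2.97 against 14.2 ± 5.12, while Ccl11, an eosinophil chemokine, stood higher at 10.5 ± 2.03 against 4.16 ± 2.43. Hair follicle transcripts took 0.588% of saliva immune replicate 2. The means of 6 of the 9 lists moved by over 1.5 times without a library. Leaving out first exposure replicate 2 moved the mean to -0.11 for type 2, -0.18 for basal keratinocyte and -0.16 for sebocyte genes. Leaving out saliva immune replicate 2 gave a mean of -0.03 for type 2, -0.04 for basal keratinocyte, -0.02 for hair follicle, -0.12 for sebocyte and 0.41 for cell cycle genes. The mean without saliva immune replicate 3 was -0.27 for type 2, -0.61 for basal keratinocyte, -0.66 for hair follicle, -0.49 for sebocyte, 0.25 for fibroblast and 0.06 for cell cycle genes. Means that moved as well were -0.41 for type 2 and -0.08 for hair follicle genes without first exposure replicate 1, -0.01 for type 2 genes without first exposure replicate 3 and -0.14 for sebocyte and 0.12 for cell cycle genes without saliva immune replicate 1.

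limma called 0 genes between saliva immune and first exposure skin, with 351 at an unadjusted p under 0.05 and 749 expected by chance; without saliva immune replicate 2 it called 1, as did the fit on CK1 alone (higher). Array weights, which did not converge, gave 2174 calls, 1324 higher and 850 lower. camera called 9 lists, with adjusted p from 0.000687 (mast cell) to 0.0379 (type 2 response) and from 0.86 to 0.894 with an estimated correlation, and 0 members of any of them passed when adjusted over the list alone. Without saliva immune replicate 2, adjusted p was 0.367 for macrophage, 0.0591 for mast cell, 0.42 for complement, 0.083 for basal keratinocyte, 0.0722 for hair follicle, 0.0546 for fibroblast and 0.0544 for type 2 genes. Sebocyte genes were lost without saliva immune replicate 1 (0.0523), cell cycle genes without that library (0.119), saliva immune replicate 3 (0.171) or first exposure replicate 2 (0.105), and hair follicle genes without first exposure replicate 1 (0.633). Type 2 (0.468), complement (0.0845) and fibroblast genes (0.116) were lost without first exposure replicate 3, type 2 (0.072) and complement (0.0533) without first exposure replicate 2, and type 2 (0.196) and fibroblast genes (0.175) without saliva immune replicate 3. Complement (0.0666) and fibroblast genes (0.0713) were also lost with the muscle covariate.

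Skin of the 2 bites group was compared with the single naive library of EF19-5, naive replicate 3. Macrophage genes differed most among the immune lists (mean log2 difference 1.42 against a median of -0.06 over all genes, 14 of 14 members), with the scavenger receptor CD163 at 112 ± 104 TPM (n = 2) against 14.8 in the naive library. The calls of this and the other lists rest on the preset correlation of camera, and none remained with an estimated correlation (adjusted p = 0.86 to 0.898). Mast cell and basophil genes (0.95) lay higher, with HDC at 3.91 ± 0.176 against 0.248, the cytokine receptor subunit Csf2rb at 15.5 ± 9.31 against 2.05 and the mast cell chymase Cma1 at 7.68 ± 5.99 against 0.627. Neutrophil (1.03), T cell (0.70), cytotoxic and natural killer cell (0.74), dendritic and Langerhans cell (0.46) and inflammatory cytokine genes (0.60) were higher, with the granzyme GZMK at 1.45 ± 0.148 against 0.0652. So were the interferon gamma (0.75) and type I interferon lists (0.81), with the antiviral enzyme OAS1 at 6.73 ± 4.65 against 1.58 and RSAD2 at 2.70 ± 1.13 against 0.432. Matrix remodelling enzymes (0.68), complement and coagulation (0.72) and endothelial genes (0.74) lay higher, with the gelatinase MMP9 at 21.0 ± 7.80 against 2.56 and the stromelysin MMP3 at 8.35 ± 4.70 against 0.751. Epidermal differentiation (0.61) and sebocyte genes (0.25) were higher, with the suprabasal keratin KRT2 at 2446 ± 1227 against 336. Skeletal muscle (-1.38), hair follicle (-0.72, 18 of 18 members) and immediate early genes (-0.59) lay lower, the muscle share being 0.562% and 0.754% against 2.20% in the naive library and the hair follicle share 1.03% and 3.24% against 2.94%. With 2 libraries in the group, each moved means by over 1.5 times. Leaving out 2 bites replicate 1 moved the mean to 0.68 for neutrophil, 0.36 for T cell, 0.81 for macrophage, 0.26 for complement, 0.36 for epidermal differentiation, 0.45 for matrix enzyme and 0.37 for endothelial genes. Leaving out 2 bites replicate 2 gave a mean of 1.14 for inflammatory cytokine, 1.18 for complement, -1.54 for hair follicle and 1.11 for endothelial genes.

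limma called 2 genes in 2 bites against naive skin, both higher, with 879 at an unadjusted p under 0.05. With no filter it called 37, 6 higher and 31 lower, and without the experiment term 254, 145 higher and 109 lower. The muscle covariate, the fit on EF19-5 alone and leaving out naive replicate 2 with 2 bites replicate 1 gave 1 each. The naive arm is 1 library, so the makeup of that biopsy and an effect of the bites cannot be told apart in the calls of genes or lists. ENSCPOG00000008260 had an adjusted p of 1.92e-08. LITAFD, named after its domain shared with the LITAF protein, was listed at 0 in all naive and first exposure libraries and stood at 5.45 ± 1.94 TPM in 2 bites skin, 3.21 ± 0.0877 in 3 bites and 1.27 ± 0.199 in saliva immune skin (adjusted p = 0.036). LITAFD passed in 8 of 22 other fits, with adjusted p of up to 0.778, and in 1 of the 12 that left out a library. The count was 2 without first exposure replicate 3, 3 without 2 bites replicate 2 and 1 without any other library. camera called 17 lists, 14 higher and 3 lower, with adjusted p from 2.23e-07 (skeletal muscle) to 0.0331 (sebocyte; dendritic cell) and from 0.86 to 0.898 with an estimated correlation. Adjusted over the list alone, 2 neutrophil, 2 mast cell, 1 interferon gamma, 1 type I interferon and 2 muscle genes passed, and 0 in the other 12 lists. Without 2 bites replicate 1, adjusted p was 0.531 for inflammatory cytokines (mean 0.06), 0.124 for dendritic cell, 0.273 for hair follicle (mean 0.09) and 0.0579 for sebocyte genes, and without 2 bites replicate 2 it was 0.0698 for sebocyte and 0.0913 for immediate early genes. With the muscle score as a covariate, the epidermal differentiation mean was -0.02 (adjusted p = 0.42) and the sebocyte mean -0.21 (0.902), and dendritic cell (0.164), hair follicle (0.154) and immediate early genes (0.515) were not called either, while the means of T cell (0.28) and interferon gamma genes (0.34), still called, were smaller.

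Skin of the 3 bites group was compared with the same naive library. Type I interferon genes lay higher (mean log2 difference 0.86 against a median of 0.08 over all genes, 12 of 12 members), with OAS1 at 10.1 ± 5.32 TPM (n = 2) against 1.58, the ubiquitin-like ISG15 at 25.9 ± 17.4 against 7.75 and RSAD2 at 1.99 ± 0.0750 against 0.432. No list of this comparison was called by camera with an estimated correlation (adjusted p = 0.86 to 0.894 for the lists called at the preset). Basal keratinocyte genes (0.73, 10 of 10) lay higher, with the hemidesmosomal collagen COL17A1 at 297 ± 89.5 against 105, as did mast cell (0.63) and endothelial genes (0.47), with MS4A2, a chain of the IgE receptor, at 6.58 ± 5.32 against 2.44 and the tight junction protein CLDN5 at 8.75 ± 4.04 against 3.93. Oxidative phosphorylation (-0.20, 24 of 24 members), hair follicle (-0.40), skeletal muscle (-0.86), melanocyte (-0.82) and immediate early genes (-0.10) lay lower, the muscle share being 1.38% and 0.703% against 2.20%. The 3 bites libraries differed from each other in melanocyte genes (list means 1.07 and 4.48 against 3.59 in the naive library) and in macrophage genes (4.90 and 2.97 against 3.58). Leaving out 3 bites replicate 2 moved the mean by over 1.5 times, to 0.47 for basal keratinocyte, -0.51 for skeletal muscle, 1.13 for endothelial, -2.52 for melanocyte and -0.38 for immediate early genes.

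limma called 1 gene in 3 bites against naive skin, ENSCPOG00000008260 (adjusted p = 5.68e-08), with 351 at an unadjusted p under 0.05 and 3 calls without 3 bites replicate 2. With no filter it called 30, 3 higher and 27 lower, and without the experiment term 2, both higher. Here too the naive arm is 1 library, whose makeup and an effect of the bites cannot be told apart. camera called 9 lists, 4 higher and 5 lower, with adjusted p from 2.17e-08 (skeletal muscle) to 0.0492 (immediate early) and from 0.86 to 0.894 with an estimated correlation, and 1 type I interferon gene passed when adjusted over the list alone, with 0 in the other 8 lists. Without 3 bites replicate 1 the melanocyte mean turned to 0.88 (adjusted p = 0.0218), the endothelial mean to -0.18 (0.314) and the immediate early mean to 0.19 (0.741), and the mast cell mean was 0.36 (0.399). Basal keratinocyte genes were lost without 3 bites replicate 2 (0.0599), and immediate early genes without first exposure replicate 1 (0.0531) or 2 (0.0527), saliva immune replicate 1 (0.0534) or 3 (0.0607), or 2 bites replicate 1 (0.054). With the muscle score as a covariate, the oxidative phosphorylation mean was 0.03 (adjusted p = 0.374) and the immediate early mean -0.14 (0.25), and the basal keratinocyte (0.34), hair follicle (-0.65) and melanocyte means (-1.29) moved by over 1.5 times with the lists still called.

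The 3 bites and 2 bites groups were compared directly. All 12 lists that camera called at the preset correlation lay lower in 3 bites skin, where the median over all genes was 0.14, and 0 of them were called with an estimated correlation (adjusted p = 0.86 to 0.898). Macrophage genes differed by -1.07 (13 of 14 members lower), with the C1q chain C1QA at 28.3 ± 28.8 TPM in 3 bites (n = 2) against 148 ± 84.0 in 2 bites skin (n = 2). Neutrophil (-0.74), cytotoxic and natural killer cell (-0.57), T cell (-0.41), mast cell (-0.32), interferon gamma (-0.28) and inflammatory cytokine genes (-0.28) lay lower, with HDC at 0.941 ± 0.853 against 3.91 ± 0.176, CD3D, a T cell receptor chain, at 1.51 ± 0.670 against 4.42 ± 1.56 and SOCS1, an inhibitor of cytokine signalling, at 6.54 ± 0.601 against 13.6 ± 1.29. The dendritic and Langerhans cell list had a mean of -0.23 but a median of 0.05. Matrix remodelling enzymes (-0.48) and complement and coagulation genes (-0.48) were lower, with MMP9 at 2.94 ± 2.73 against 21.0 ± 7.80 and PLAUR, the urokinase receptor, at 5.00 ± 2.35 against 14.4 ± 7.33. Melanocyte (-1.38) and endothelial genes (-0.26) were lower too, with GPR143, a receptor of pigment cell organelles, at 2.77 ± 3.91 against 10.4 ± 6.52. All 12 means moved by over 1.5 times without a library. Leaving out 2 bites replicate 1 moved the mean to -0.39 for neutrophil, -0.11 for mast cell, -0.06 for T cell, -0.36 for cytotoxic cell, -0.46 for macrophage, -0.09 for dendritic cell, -0.02 for complement and -0.25 for matrix enzyme genes. Leaving out 3 bites replicate 1 gave a mean of -0.59 for mast cell, -2.04 for macrophage, -0.93 for complement, -0.93 for matrix enzyme and -0.92 for endothelial genes. The mean without 3 bites replicate 2 was -0.04 for mast cell, -0.13 for dendritic cell, -0.57 for interferon gamma, -0.04 for complement, -0.03 for matrix enzyme and -3.08 for melanocyte genes. Leaving out 2 bites replicate 2 moved the mean to -0.52 for mast cell, -0.76 for T cell, -1.69 for macrophage, -0.38 for dendritic cell, -0.81 for inflammatory cytokine, -0.94 for complement and -0.63 for endothelial genes.

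limma called 0 genes between 3 bites and 2 bites skin (smallest adjusted p = 0.179), with 1615 at an unadjusted p under 0.05, and called 4 without 3 bites replicate 2 and 1 without 2 bites replicate 2. With the muscle covariate it called 518, 481 higher and 37 lower, while the 12 called lists all lay lower, and with no filter 4, all lower. Adjusted p of the 12 lists ran from 3.45e-06 (macrophage) to 0.049 (inflammatory cytokines) by camera and from 0.86 to 0.898 with an estimated correlation. Adjusted over the list alone, 2 matrix enzyme, 1 mast cell and 1 interferon gamma gene passed, and 0 in the other 9 lists. Without 3 bites replicate 2, adjusted p was 0.351 for macrophage (mean -0.11), 0.224 for mast cell, 0.152 for dendritic cell, 0.395 for complement, 0.225 for matrix enzyme and 0.0576 for endothelial genes (mean 0.39). Without 2 bites replicate 1 it was 0.0777 for mast cell, 0.121 for T cell, 0.158 for dendritic cell, 0.973 for inflammatory cytokine (mean 0.26), 0.188 for complement and 0.586 for endothelial genes (mean 0.11). Without 3 bites replicate 1 it was 0.904 for melanocyte (mean 0.32), 0.327 for interferon gamma (mean 0.01, 0.005 before rounding) and 0.151 for inflammatory cytokine genes. Melanocyte genes were lost without 2 bites replicate 2 (0.0897), dendritic genes without saliva immune replicate 3 (0.0511), and inflammatory cytokine genes without first exposure replicate 2 (0.0531), saliva immune replicate 2 (0.0527) or naive replicate 3 (0.0539). Dendritic cell (0.14) and interferon gamma genes (0.0624) were lost with the muscle covariate, and the T cell mean was -0.25 with it.

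Repeat bites (2 bites and 3 bites, 4 libraries) and first exposure come from different experiments, so each was taken relative to the naive skin of its own experiment and the differences were compared. Adipocyte genes lay lower after repeat bites (mean log2 difference of differences -1.92 against a median of -0.10 over all genes, 10 of 11 members). As in the other comparisons, the list calls were lost with an estimated correlation (camera adjusted p = 0.86 to 0.909). LEP stood at 807 ± 44.7 TPM in 2 bites and 1032 ± 663 in 3 bites skin against 1267 in the EF19-5 naive library, and at 2839 ± 1455 in first exposure against 321 ± 114 in CK1 naive skin. Cell cycle genes lay higher (0.53, 23 of 23), with RRM2 at 29.6 ± 0.439 in 2 bites and 22.9 ± 1.78 in 3 bites skin against 23.2, and 14.8 ± 2.19 in first exposure against 25.5 ± 4.19. As a difference of differences, immediate early (0.51), mast cell (0.42), type I interferon (0.37) and endothelial genes (0.25) lay higher. Hair follicle (-0.78, 17 of 18) and ribosomal protein genes (-0.22, 22 of 22) lay lower on the same scale. Immediate early genes lay below naive skin after both kinds of exposure. Their list mean was 6.479 in 2 bites and 6.969 in 3 bites skin against 7.065, and 6.783 in first exposure against 7.637. KRT75, a keratin of the hair follicle, stood at 983 ± 544 and 987 ± 45.7 TPM in 2 bites and 3 bites skin against 1713, and at 1130 ± 247 in first exposure against 710 ± 226. Naive replicate 3, on which the repeat bite values rest, held 2.20% muscle and 2.94% hair follicle transcripts, and the CK1 naive libraries 8.93% and 15.6% muscle transcripts. All means but those of adipocyte, cell cycle and ribosomal genes moved by over 1.5 times without a library. Leaving out naive replicate 1 moved the mean to 0.21 for mast cell, 0.19 for type I interferon, -1.25 for hair follicle and 0.10 for immediate early genes. Leaving out 2 bites replicate 1 gave a mean of 0.25 for type I interferon, -0.37 for hair follicle and 0.07 for endothelial genes. The mean without naive replicate 2 was -0.30 for hair follicle, 0.53 for endothelial and 0.92 for immediate early genes. Other means were 0.24 for type I interferon and 0.58 for endothelial genes without 3 bites replicate 2, -0.48 for hair follicle and 0.43 for endothelial genes without first exposure replicate 1 and -1.18 for hair follicle and 0.44 for endothelial genes without 2 bites replicate 2. The mean was 0.16 for endothelial genes without first exposure replicate 2.

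limma called 0 genes for repeat bites against first exposure (smallest adjusted p = 0.501), with 497 at an unadjusted p under 0.05, and called 1 without 3 bites replicate 2. With no filter it called 24, 2 higher and 22 lower, and without the experiment term 14, 6 higher and 8 lower. camera called 8 lists, with adjusted p from 8.51e-12 (cell cycle) to 0.0444 (endothelial) and from 0.86 to 0.909 with an estimated correlation, and by fry 0 of 32 passed at an unadjusted p under 0.05. Adjusted over the list alone, 2 adipocyte genes passed, both lower, and 0 in the other 7 lists. Without naive replicate 1, adjusted p was 0.0591 for mast cell, 0.0724 for type I interferon, 0.229 for endothelial (mean -0.02), 0.122 for immediate early and 0.598 for ribosomal genes. Hair follicle genes were lost without first exposure replicate 1 (0.366), naive replicate 2 (0.146), 3 bites replicate 2 (0.0604) or 2 bites replicate 1 (0.51). Endothelial and ribosomal genes were lost without first exposure replicate 2 (0.202 and 0.0806) or 3 (0.138 and 0.169), saliva immune replicate 2 (0.0598 and 0.0547) or 3 (0.0549 and 0.0665), 3 bites replicate 1 (0.819, mean -0.07, and 0.148) or 2 bites replicate 1 (0.182 and 0.223). With the muscle covariate, hair follicle and ribosomal genes were not called (adjusted p = 0.171 for each).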

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

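The tests of muscle content and of the naive libraries were chosen only after the results were seen; the counts of splits were set before. The difference between repeat bites (2 and 3 bites, each relative to the naive skin of EF19-5) and first exposure (relative to that of CK1) was tested as an interaction, and camera at the preset correlation called 8 lists, which drew attention because their bite effects differed between exposures. The mean log2 difference of differences was 0.416 for mast cell and basophil, 0.371 for type I interferon, 0.253 for endothelial cell and 0.514 for immediate early and stress genes. It was -0.775 for hair follicle and -0.224 for ribosomal protein genes. With an estimated correlation the adjusted p of the 8 lists lay between 0.86 and 0.909. By limma 0 genes were called, with 497 at an unadjusted p under 0.05. Any split calls at least the real 0 genes (35 of 35, highest other 0), so that count says nothing. Of the 35 splits, 32 called at least the real 6 lists (adjusted within the comparison; highest other 17); they exchange libraries between the experiments, so they cannot exclude chance.

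The adipocyte list (-1.918, SE 0.828) and the cell cycle list (0.526, SE 0.317) had the smallest camera p of the 8. With the skeletal muscle score as a covariate, the adipocyte difference was -2.021 (SE 0.878), which argues against muscle content of the biopsies as its whole cause. The cell cycle difference was 0.462 (SE 0.316) with the score and camera still called the list (adjusted p = 7.08e-08), but what is left beyond 50% of 0.526 is smaller than its SE, so muscle content stays open there. The naive library of EF19-5 lay 0.777 above the mean of the CK1 naive libraries in adipocyte genes and 0.116 above it in cell cycle genes. With 1 naive library in EF19-5, a difference in the makeup of that biopsy and an effect of repeat bites cannot be told apart, and an effect of repeat exposure, which may also give such differences, stays open.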

How the results depend on the processing

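Of the alternatives, the skeletal muscle score as a covariate and leaving out naive replicate 2 with 2 bites replicate 1 were chosen only after the results were seen. ENSCPOG00000008260 passed in all other fits of the 5 comparisons that tested it against naive skin. No paired analysis was possible because the titles give no 2 groups the same 2 replicate numbers. Of each change given here, the cause was not tested. Own-experiment fits gave no value for bitten against naive or repeat bites against first exposure, leaving out naive replicate 3 gave none for 2 bites or 3 bites against naive or repeat against first exposure, and the skeletal muscle list has none under its own covariate. TPM keeps no depth, so the precision of low genes is unknown.

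Called genes, with 6, 5, 1, 0, 2, 1, 0 and 0 in bitten, first exposure and saliva immune against naive, saliva immune against first exposure, 2 bites and 3 bites against naive, 3 against 2 bites and repeat against first exposure, varied as follows. A pseudocount of 0.1 gave 12 in bitten (11 higher, 1 lower) and 5 in saliva immune skin. No filter gave 3 in first exposure, 2 in saliva immune, 37 in 2 bites, 30 in 3 bites, 4 in 3 against 2 bites and 24 in repeat bites. Median-of-ratios scaling gave 3 in saliva immune skin, and quantile normalization 3 in bitten and 4 in saliva immune skin. Without the experiment term the counts were 3 in bitten, 1 in first exposure, 2 in saliva immune, 254 in 2 bites, 2 in 3 bites skin and 14 in repeat bites. Each experiment alone gave 1 in saliva immune against first exposure and 1 in 2 bites skin. Array weights gave 92 in bitten skin, with weights of 0.445 to 2.65, and 20 in saliva immune against naive and 2174 against first exposure, in a fit whose weights did not converge (up to 51.9 for saliva immune replicate 1). The muscle covariate gave 3 in bitten, 37 in first exposure, 7 in saliva immune, 1 in 2 bites skin and 518 in 3 against 2 bites. Leaving out both libraries gave 1 in bitten, 2 in first exposure, 2 in saliva immune and 1 in 2 bites skin. Leaving out each library in turn gave 1 to 31 in bitten (31 without 3 bites replicate 1), 1 to 19 in first exposure (19 without saliva immune replicate 3), 1 to 6 in saliva immune (6 without either 3 bites library), 0 to 1 in saliva immune against first exposure (1 without saliva immune replicate 2), 1 to 3 in 2 bites (3 without 2 bites replicate 2), 1 to 3 in 3 bites (3 without 3 bites replicate 2), 0 to 4 in 3 against 2 bites (4 without 3 bites replicate 2) and 0 to 1 in repeat bites (1 without 3 bites replicate 2).

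Of the 96 lists called, 0 were called by camera with an estimated correlation and 0 by fry (23 at an unadjusted p under 0.05), 68 of the 91 with a value were called in the same direction with the muscle covariate and 69 without both libraries. With a pseudocount of 0.1, 90 of 96 were, with no filter 87, with a filter on mean TPM 87 of 94, with median-of-ratios scaling 78, with quantile normalization 79, without the experiment term 78, with array weights 76 and within each experiment alone 66 of 70. With 1 library left out, 75 (without saliva immune replicate 2) to 93 (without first exposure replicate 1) were, and 52 of 62 without naive replicate 3, where 3 comparisons have no value. Counted over all pairs with a value, calls ran from 52 there to 112 (without 3 bites replicate 2). List means turned sign as follows. Without the experiment term, skeletal muscle was 0.198 and oxidative phosphorylation 0.032 in first exposure, skeletal muscle 0.132 and smooth muscle 0.155 in saliva immune, hair follicle 0.303 in 3 bites skin, and hair follicle 0.284, endothelial -0.224, immediate early -0.059 and ribosomal 0.021 in repeat bites against first exposure. Array weights gave 0.093 for skeletal muscle in saliva immune skin. With the muscle covariate, oxidative phosphorylation was 0.119 in bitten, 0.082 in first exposure and 0.029 in 3 bites skin, and epidermal differentiation -0.022 and sebocyte -0.213 in 2 bites skin. Without both libraries, epidermal differentiation was -0.011 and oxidative phosphorylation 0.058 in first exposure, hair follicle 0.094 in 2 bites skin, inflammatory cytokines 0.26 and endothelial 0.106 in 3 against 2 bites, and hair follicle 0.11 in repeat bites. Means that turned when 1 library was left out ranged as follows, with the library at each turned end. Hair follicle ran from -0.505 to 0.025 (naive replicate 3) in bitten, from -0.637 to 0.315 (naive replicate 1; 0.191 without saliva immune replicate 2) in saliva immune and from -1.542 to 0.094 (2 bites replicate 1) in 2 bites skin. In first exposure, epidermal differentiation ran from -0.011 (naive replicate 2) to 1.224, and oxidative phosphorylation from -0.189 to 0.058 (naive replicate 2; 0.002 without first exposure replicate 2). In saliva immune skin, skeletal muscle ran from -1.037 to 0.15 (saliva immune replicate 3) and smooth muscle from -0.385 to 0.02 (naive replicate 1). In 3 bites skin, endothelial ran from -0.182 (3 bites replicate 1) to 1.125, melanocyte from -2.52 to 0.882 (3 bites replicate 1) and immediate early from -0.382 to 0.191 (3 bites replicate 1). In 3 against 2 bites, inflammatory cytokines ran from -0.812 to 0.26 (2 bites replicate 1), interferon gamma from -0.566 to 0.005 (3 bites replicate 1), endothelial from -0.917 to 0.39 (3 bites replicate 2; 0.106 without 2 bites replicate 1) and melanocyte from -3.079 to 0.323 (3 bites replicate 1). Endothelial in repeat bites ran from -0.073 (3 bites replicate 1; -0.022 without naive replicate 1) to 0.58.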

Other observations

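The tests of the immune and resident scores, of the muscle covariate and of the genes listed at 0, and the splits within experiments, were chosen only after the results were seen; the tests of genes and lists and the other splits were set before. CCL17, a chemokine that attracts T cells bearing CCR4 and belongs to the type 2 response list, was listed at 0 in all 3 naive libraries and lay between 1.81 and 11.4 TPM in the 10 bitten ones. Its log2 fold change in bitten against naive skin was 2.43 (SE 0.451), with an adjusted p of 0.0729 by limma, so it was not called over all genes; adjusted over the list alone it was the 1 type 2 gene that passed. The type 2 list as a whole had a mean log2 difference of 0.44 in bitten skin (11 of 14 members higher; camera adjusted p = 0.281). Of the cytokines in the fixed panel, Cxcl8, a neutrophil chemokine, stood at 3.49 ± 3.82 TPM in bitten (SD, n = 10) and 0.553 ± 0.263 in naive skin (n = 3), Il1b at 5.25 ± 4.96 against 2.02 ± 1.38 and Tnf at 2.59 ± 0.950 against 1.34 ± 0.720, none of them called (limma adjusted p = 0.294, 0.466 and 0.277). FOXP3, the factor of regulatory T cells, stood at 0.812 ± 0.3 against 0.624 ± 0.0686 (limma adjusted p = 0.73). The eosinophil peroxidase EPX and the myeloperoxidase MPO were listed at 0 in every library, and IL4, IL13, IL10, IFNG, IL17A and CD8A stayed below the filter, with highest values of 0.59, 3.58, 1.79, 0.159, 0.507 and 1.4 TPM. IL6, CD4, KRT6A and FLG were not measured here.

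Among the 32 tested lists, 6 were called in none of the 8 comparisons, with smallest camera adjusted p of 0.0558 for the regulatory response, 0.065 for itch, histamine and pain sensing, 0.0977 for type 17, 0.104 for B cell and plasma cell, 0.11 for activated keratinocyte and 0.6 for nerve and Schwann cell genes. The eosinophil list had 0 measured members and the erythroid and platelet list 4, so neither was tested. The 3 bites libraries differed from each other most in melanocyte genes, with list means of 1.07 in replicate 1 and 4.48 in replicate 2 against 3.59 in the naive library of EF19-5.

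The difference between 7 immune and 10 resident skin lists was examined because the muscle share differed between bitten and naive libraries, and less muscle would raise every other cell type alike. The immune lists lay 0.582 higher in bitten skin (exact permutation p = 0.0143, two-sided, adjusted p = 0.0858 over 24 scores). The smallest permutation p possible was 0.00714, at which 1 score alone could not pass that adjustment. The resident lists lay 0.261 higher (exact permutation p = 0.164). The 2 kinds of list did not move apart beyond chance (difference 0.321, exact permutation p = 0.186). With the muscle score as a covariate the immune score lay 0.482 higher (SE 0.221) and the resident score 0.076 (SE 0.141), and camera at the preset correlation still called 4 of 4 immune cell and 3 of 6 resident lists, of which 0 were called with an estimated correlation even without the covariate (adjusted p = 0.86 to 0.898). What is left of the immune difference beyond 50% of 0.582 is smaller than its SE. Within EF19-5 the immune lists lay 0.552 higher, with a muscle share of 2.20% in the naive library and 0.562% to 1.38% in the bitten ones. That difference rests on 1 naive library, so it cannot decide, and a lower muscle share stays open. Within CK1, which does not hold 2 bites replicate 1, the immune lists lay 0.599 higher (exact permutation p = 0.0357, the smallest p possible), which argues against that library as the whole cause, and an immune response to bites, which may give the same pattern, stays open.

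ENSCPOG00000008260, listed at 0 in the naive libraries and at 422 TPM or more in the bitten ones, has no symbol, and what it encodes was not examined. Zeros that fall by chance on 3 libraries may give other sets of 3 as many such genes. Leaving this gene out, 2 of the 286 sets had 2 genes at 0 in them alone and at 1 TPM or more in the rest, the naive set (CCL17 and ENSCPOG00000036317) and first exposure replicate 1 with naive replicates 1 and 2. Such genes lie near the floor, so this count cannot decide for a gene at 422 TPM or more in the bitten libraries. A test of this gene alone would run on a gene chosen for its zeros, so chance zeros stay open. A failed estimate of the gene in the naive libraries may give the same zeros and stays open. Of 1477 genes with a median of at least 100 TPM in bitten libraries, 1 other was listed at 0 in a naive library. That gene, ENSCPOG00000000748, named here after its values were seen, has no symbol either. It stood at 0 in naive replicates 1 and 2 and in first exposure replicate 1, and at 1.36 TPM in naive replicate 3. In the other bitten libraries it lay between 13.1 and 976 TPM. Failure of a single gene would leave no trace in the rest.

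In bitten against naive skin, 3 of 100 splits of the same libraries, the real one included, called at least the real 6 genes and 4 of 100 at least the real 20 lists (adjusted within the comparison; highest other 24). Other splits kept 2 CK1 libraries and 1 of EF19-5 in the naive place, as in the design. Of 100 such splits, 3 called at least 6 genes (highest other 2220) and 5 at least 20 lists (highest other 21). The share lies under 0.05 for genes but not for lists. Some other splits reached far more genes than the real one. The real count also fell to 1 without first exposure replicate 3 or naive replicate 2, so chance is not excluded for either count. The splits with 656 genes (saliva immune replicate 2, naive replicate 2 and 2 bites replicate 1 against the rest) and 2220 (first exposure replicate 2, saliva immune replicate 3 and 3 bites replicate 2) point to a structure of the samples, whose cause was not tested. The splits of first exposure and of saliva immune against naive skin exchange naive replicate 3 of EF19-5 with CK1 libraries, so they do not keep the experiments apart. For first exposure against naive skin, splits are also too few for a share under 0.05. Of 10 splits, 1 reached the real 5 genes (highest other 1) and 4 the real 11 lists (highest other 19). The same limit holds for saliva immune against naive skin (3 of 10 at the real 1 gene, highest other 2; 2 of 10 at the real 17 lists, highest other 17) and saliva immune against first exposure skin (5 of 10 at the real 9 lists, highest other 16), where any split reaches the real 0 genes (10 of 10, highest other 1), so that count says nothing.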
